A study of Mus musculus with 12 samples.

How the data were processed

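Ter-119 positive cells were selected magnetically from the spleens of male F1 adults (CBA and C57BL/6 parents), and RNA from 500000 cells per sample was counted on the nCounter Mouse Immunology v1 panel, per the labels' protocols and the series' design text. Spleens were taken on day 3 from normal mice, from mice after acute blood loss and from mice after acute hypoxia. Groups were taken from the condition in the labels. The labels do not say which sample came from which animal, so p-values measure the spread between samples, which may be partly technical.

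The authors deposited raw counts, whole numbers with a lowest value of 1, for 561 genes in 12 columns. Of these genes 14 are the panel's housekeeping genes and 547 are endogenous. Positive and negative control probes were not used here, and 1 column of the 12 entered only the 12-sample fit. The authors also deposited a normalized count signal, which equals the raw count divided by the DESeq2 median-of-ratios size factor of its sample (largest relative difference 8.88e-16), as computed here from the values. The deposited log2 value table holds log2 of that normalized count plus 1, within 0.00500 of the value recomputed here. The handling of background and the software of the counting step are not given in the sources used here.

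The deposited column of Normal 4 was left out of the 11-sample fit reported here. In all 561 genes its raw count equals the median of Normal 1, Normal 2 and Normal 3 plus 3, so it carries no measurement of its own in these values. Among the other columns, apart from the Normal 2 and Normal 4 pair, at most 8.57% of genes with a count of 20 or more lay at a single constant difference from another column or from a summary of 2 or 3 columns. The design fixed before the data were examined put all 12 samples in the fit. Leaving out 1 column departs from it and was decided after the counts were seen, so the 12-sample counts of calls stand beside the 11-sample counts in the report.

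Raw counts of 3 normal, 4 blood loss and 4 hypoxia samples were fitted together with the quasi-likelihood test of edgeR 4.0.16 (robust) in R 4.3.3, with group as the only term. Library factors were the geometric mean of the 6 housekeeping genes with a mean raw count of at least 100 (Eef1g, Gapdh, Oaz1, Polr2a, Ppia and Rpl19). These genes were not steady after scaling. Between normal and blood loss samples the mean scaled count of Eef1g went from 661 to 347 and that of Polr2a from 203 to 388. Rpl19 stood at 2286, 450 and 1022 in Normal 1, Normal 2 and Normal 3. An endogenous gene was tested where its raw count was 20 or more in at least 4 samples, which left 252 genes. Since there are 3 normal samples, this filter cannot pass a gene seen only in normal samples, and 13 genes had a count of 20 or more in all 3 normal and in none of the treated samples. With the filter at 3 samples 282 genes were tested, and of these 13 genes 5 were called lower after blood loss and 11 after hypoxia. The design named a threshold from negative control probes first and a raw count of 20 where these could not be used. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are housekeeping-scaled counts, given as mean ± SD over the samples of a group. Standard errors of log2 fold changes were derived from the fold change and the test statistic. The fit was tested on simulated counts with known changes. In the simulated comparison of blood loss with normal, 60.7% of 2-fold and 93.0% of 4-fold changes were recovered among 294 genes, with 1.70% of unchanged genes called. The simulated comparison of hypoxia with normal gave 66.2%, 100% and 5.46% among 311 genes. The simulated comparison of hypoxia with blood loss gave 72.3%, 100% and 2.72% among 311 genes. Genes were drawn independently around a common mean, so these simulations leave out differences between the real normal samples that many genes share. The rates may therefore not hold for the real comparisons with normal.

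The design also fixed 24 gene lists, of which 21 had at least 3 tested members. Lists were tested with camera at a preset inter-gene correlation of 0.01 and at an estimated correlation, and with fry (limma 3.58.1), with adjustment over the lists within a comparison. Camera compares a list with the other genes. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

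Genes to be named were fixed by a rule: in each comparison the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a count of 20 or more in all samples of at least 1 of the groups, 22 set genes, and up to 4 members of each list with the smallest p. The rule gave 88 genes for blood loss against normal and 89 for each other comparison. Of these, 46, 51 and 33 were followed through every alternative and are the pool from which the text names genes. That narrowing was made after their values were seen, and some genes of the pool are not reported here. Of the 22 set genes, Arg1 and Arg2 were not analysed here, and Kit, Il10 and Csf1r were under the count filter, Csf1r being among the 13 genes seen in normal samples only.

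Alternatives fixed in the design were TMM factors, DESeq2 size factors, all 14 housekeeping genes, the DESeq2 1.42.0 Wald test, limma on the deposited normalized values (log2 of the value plus 1), no count filter, a count of 20 in all samples, a fit of only the groups compared, the replicate number as a block, and leaving out each sample in turn. In the edgeR fits the factors called the deposited size factors were recomputed by the deposited method, over all genes of the 11 samples. Only limma used the deposited normalization itself, which rests on all 12 columns. The 12-sample fit of the design was kept as an alternative to the 11-sample fit. Alternatives added after the data were seen were housekeeping genes without Rpl19, size factors over the tested genes, subtraction of each sample's lower quartile, Normal 1 as the only normal sample (the lone sample assumed to vary like the treated groups), a count of 20 in at least 3 samples, counts thinned to the shallowest total, leaving out each sample with the genes of the 11-sample fit for genes that otherwise fall under the count filter, and detection at a raw count of 10 or 40. Alternatives that need control probes were not run. Some calls rest on 1 sample or on the scaling, and the report names these beside the gene or list. Same-numbered samples of different groups did not deviate together, with correlations of −0.254 to 0.130 over 10 pairs, so the numbers were not taken to pair samples. Total counts ran from 7016 to 253712, so low-count genes were measured with less precision in the blood loss samples. Intervals for shares cover counting error only.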

Results

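Splenic erythroid cells were profiled in normal mice, in mice 3 days after withdrawal of 0.5 to 0.8 mL of blood and in mice kept for 16 h in a hypobaric chamber at the pressure of more than 4500 m of altitude. Both treatments stimulate red cell production, which in the mouse extends to the spleen. Cells were selected for Ter-119, a surface protein of the red cell lineage, and the series' title concerns antigen-presenting cell transcripts in such cells that carry CD45. The panel counts barcoded probes on RNA molecules directly, without amplification, for genes chosen for their role in immunity.

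The comparisons used 3 normal, 4 blood loss and 4 hypoxia samples. The deposited column of Normal 4 was left out, because its count equalled the median of the other 3 normal samples plus 3 in all 561 genes. Total counts were 43956, 161054 and 253712 in Normal 1, Normal 2 and Normal 3. They ran from 7016 to 31006 after blood loss and from 44254 to 81370 after hypoxia. Genes with a raw count of 20 or more numbered 223 to 394 in normal, 69 to 210 in blood loss and 218 to 265 in hypoxia samples. The blood loss samples were the shallowest, and the precision for genes with low counts was lowest there.

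**Figure D1:**
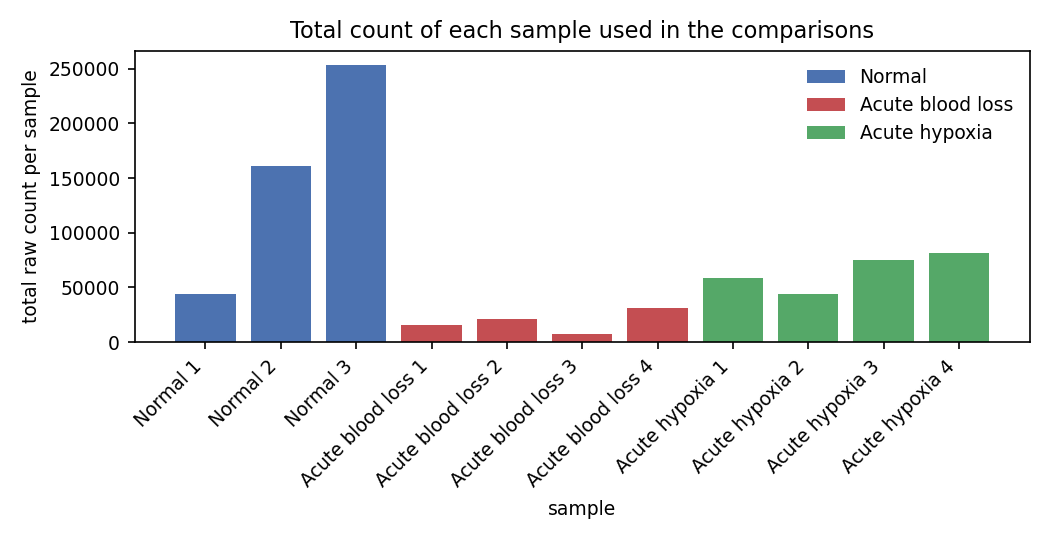
Bars give the total raw count (y axis) of each of the 11 samples used (x axis), coloured by group. Totals run from 7016 in Acute blood loss 3 to 253712 in Normal 3, and all 4 blood loss samples lie below every normal and hypoxia sample.

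Transcripts of antigen presentation were detected in all groups. Of the 10 genes of MHC class II presentation on the panel, 10 had a raw count of 20 or more in all 3 normal samples, 10 in all 4 hypoxia samples and 6 in all 4 blood loss samples. Cd74, the invariant chain that escorts class II molecules, stood at 5041 ± 1112 housekeeping-scaled counts after blood loss (SD, n = 4), 4615 ± 651 after hypoxia (SD, n = 4) and 2001 ± 2357 in normal samples (SD, n = 3). Of 8 costimulatory and checkpoint ligand genes, 5, 5 and 3 reached a count of 20 in all normal, all hypoxia and all blood loss samples. For 12 genes of MHC class I presentation these numbers were 9, 9 and 2. A raw count of 20 takes no account of depth, and the blood loss samples were the shallowest. These numbers therefore do not compare levels between groups. Ptprc, which encodes CD45, was detected in all 11 samples, at 517 ± 61.3 in normal (SD, n = 3), 330.2 ± 97.4 in blood loss (SD, n = 4) and 281 ± 26.9 in hypoxia samples (SD, n = 4).

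The normal samples differed among themselves, in whole marker lists as well as in a few abundant genes. The mean log2 housekeeping-scaled level of the B cell markers was 6.46, 7.61 and 7.35 in Normal 1, Normal 2 and Normal 3. In the same order it was 7.53, 8.46 and 8.09 for granulocyte markers and 5.10, 6.29 and 5.95 for macrophage markers. For T and NK cell markers it was 6.01, 5.59 and 5.29. Housekeeping-scaled Cd74 was 4723 in Normal 1 against 669 and 612 in Normal 2 and Normal 3. The ratio of raw Cd74 to raw H2-Eb1 was 4.75, 0.429 and 0.600 in these samples, and 5.92 to 13.0 in the 8 others. Over 125 genes the median ratio of the raw count to that in Normal 1 was 5.41 in Normal 2 and 8.69 in Normal 3, while for Cd74 these ratios were 0.520 and 0.906 and for H2-Aa 0.535 and 0.887. Fold changes of these genes against normal depend on which normal samples are used.

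After acute blood loss, erythroid and granulocyte transcripts were among the genes that rose and lymphocyte transcripts among those that fell. Tfrc, the transferrin receptor that brings iron into developing red cells, rose from 129 ± 13.6 (SD, n = 3) to 396 ± 122 (SD, n = 4; log2 fold change 1.61, SE 0.39, adjusted p = 0.00315). Camp, an antimicrobial peptide of neutrophil granules, rose from 63.2 ± 34.0 to 422 ± 137 (log2 fold change 2.71, SE 0.38, adjusted p = 1.61e-05), and S100a9, an abundant calcium-binding protein of neutrophils, rose with a log2 fold change of 1.86 (SE 0.49, adjusted p = 0.00589). Cd86, a costimulatory ligand for T cells, rose with a log2 fold change of 1.72 (adjusted p = 0.00103). H2-Eb1, a class II beta chain, fell from 1192 ± 319.7 to 429.7 ± 129 (log2 fold change −1.47, SE 0.33, adjusted p = 0.00209). Every blood loss sample lay outside the range of the normal samples in each of these 5 genes. Housekeeping-scaled S100a9 was 1178, 847 and 549 in Normal 1, Normal 2 and Normal 3, and at least 1769 after blood loss. Cd86 was 55.4, 44.1 and 33.3 in the same normal samples, and at least 86.1 after blood loss. The sizes of the rises of S100a9 and Cd86 therefore depend on the normal samples used.

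In total 25 genes were called higher and 43 lower of 252 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), with 103 at an unadjusted p under 0.05. In 27.4% of genes the groups did not overlap, against 5.71% by chance. The median log2 fold change of all tested genes was −0.24 with housekeeping scaling, 0.05 with TMM factors and −0.63 with the deposited size factors, and directions of genes with small changes depended on it. Here and below, the deposited size factors are those of the deposited method, recomputed over all genes of the 11 samples. Calls were 39 higher and 32 lower with TMM factors, 34 and 34 with size factors over the tested genes, 14 and 85 with all 14 housekeeping genes and 13 and 114 with the deposited size factors. Of the 25 genes called higher, 13 were called higher under all 5 other scalings, as were 32 of the 43 called lower. The 12-sample fit of the design called 33 higher and 73 lower. Higher calls numbered 13 without Normal 3, 14 without Acute blood loss 3 and 16 without Acute blood loss 4, and lower calls numbered 20 without Normal 2 and 26 without Acute blood loss 4.

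Of the 8 tested erythroid and progenitor genes, 2 rose, 1 fell and 5 were not called. Besides Tfrc, Tal1, a transcription factor of early erythroid cells, rose with a log2 fold change of 3.82 (SE 0.84, adjusted p = 0.00496), although its raw count was under 20 in all 3 normal samples and in 3 of 4 blood loss samples. Cd55, a regulator of complement on red cells and other cells, fell (log2 fold change −1.13, SE 0.30, adjusted p = 0.00589), a call lost without Normal 2 (log2 fold change −0.83, adjusted p = 0.0641). Adjusted over the list alone, 2 rose and 2 fell, and with the deposited size factors and with all 14 housekeeping genes 2 rose and 3 fell. Of 6 granulocyte markers, Camp and S100a9 rose, 1 fell and 3 were not called, also when adjusted over the list alone. Cd36, a scavenger receptor, rose (log2 fold change 1.39, SE 0.32, adjusted p = 0.00236), as did Plaur, which encodes the urokinase receptor (log2 fold change 1.34, SE 0.34, adjusted p = 0.0053).

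Among costimulatory and checkpoint ligands, 3 of 7 tested genes rose and none fell, and adjusted over the list alone 3 rose and 1 fell. The 3 were Cd86, Cd80 (log2 fold change 1.03, SE 0.39, adjusted p = 0.0486) and Cd274, which encodes the checkpoint ligand PD-L1 (log2 fold change 0.89, SE 0.30, adjusted p = 0.0289). The list median lay 1.02 above that of all tested genes. With the deposited size factors and with all 14 housekeeping genes 1 was called higher and 2 lower. Cd80 had a raw count under 20 in all 4 blood loss samples, so its rise rests on low counts. The calls of Cd80 and Cd274 were lost with the deposited size factors and with all 14 housekeeping genes. That of Cd80 was lost without Normal 1 (log2 fold change 0.96), Normal 2 (1.09), Normal 3 (1.08), Acute blood loss 1 (0.70), Acute blood loss 3 (0.89) or Acute hypoxia 3 (1.04), and with the count filter at 3 samples (1.05), and that of Cd274 without Normal 1 (0.64), Normal 3 (0.98), Acute blood loss 2 (0.80) or Acute blood loss 3 (0.83).

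Of 10 genes of MHC class II presentation 4 fell and 6 were not called, and adjusted over the list alone 5 fell. With the deposited size factors 7 fell and with all 14 housekeeping genes 6. The list median minus that of all tested genes was −0.45. The 4 were H2-Eb1, H2-Ab1 (log2 fold change −2.57, SE 0.64, adjusted p = 0.01), H2-Ob (log2 fold change −1.42, SE 0.29, adjusted p = 0.00103) and the protease gene Ctss (log2 fold change −1.48, SE 0.29, adjusted p = 0.000709). Cd74 and H2-Aa had positive log2 fold changes that did not pass, 1.34 (adjusted p = 0.117) and 0.97 (adjusted p = 0.238). Without Normal 1 both were called higher (2.98 and 2.61), and H2-Ab1 was still called lower, at −0.77. The call of H2-Ab1 was lost in a fit of only the 2 groups compared (−2.57) and after thinning all samples to the shallowest total (−2.47), and the DESeq2 Wald test gave no p-value for H2-Ab1 or H2-Aa (−2.58 and 0.97). Of 10 tested class I genes, H2-K1 fell (log2 fold change −1.34, SE 0.28, adjusted p = 0.00112) and 9 were not called, also when adjusted over the list alone, and 4 fell with the deposited size factors and with all 14 housekeeping genes.

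Among T and NK cell markers 6 of 13 fell and 1 rose, both before and after adjustment over the list alone. Lower calls numbered 2 with TMM factors, 3 with size factors over the tested genes, 4 without Rpl19, 7 with all 14 housekeeping genes and 8 with the deposited size factors. Cd3d, a subunit of the T cell receptor complex, had a log2 fold change of −1.78 (adjusted p = 0.00236) and the T cell transcription factor gene Tcf7 one of −1.62, adjusted p = 0.00195. Cd3d reached a raw count of 20 in 0 and Tcf7 in 1 of 4 blood loss samples, so the sizes of these changes rest on low counts, and Cd3d stood at −2.47 without Acute blood loss 2. The costimulatory receptor gene Cd28 rose (log2 fold change 1.27, SE 0.40, adjusted p = 0.0208), with a raw count of 20 or more in 1 of 4 blood loss samples, a call lost without Normal 3 (1.01) or Acute blood loss 4 (1.09). The list median minus that of all tested genes was −0.52. Of 14 B cell markers 4 fell and 10 were not called, and adjusted over the list alone 5 fell. With the deposited size factors 9 fell and with all 14 housekeeping genes 6. The mean log2 level of the B cell markers in Normal 1, 6.46, lay within the 5.90 to 6.94 of the blood loss samples. Ms4a1, which encodes CD20, fell (log2 fold change −1.05, SE 0.33, adjusted p = 0.0208), as did the B cell receptor subunit gene Cd79b (log2 fold change −1.31, SE 0.29, adjusted p = 0.00188). The call of Ms4a1 was lost without Normal 2 (−0.90), Normal 3 (−0.96), Acute blood loss 1 (−0.89) or Acute blood loss 4 (−1.03). Of 16 tested NF-kappaB and inflammatory cytokine genes 1 rose, 2 fell and 13 were not called, and of 4 chemokine genes 1 rose and 2 fell, both also when adjusted over the list alone. Of the 16 genes 3 rose and 2 fell with TMM factors, 0 rose and 5 fell with the deposited size factors and 0 rose and 4 fell with all 14 housekeeping genes. The chemokine gene that rose was not called higher under the last 2 scalings. Genes that fell included Il1b (log2 fold change −2.11, SE 0.56, adjusted p = 0.0146), the chemokine gene Ccl5 (log2 fold change −2.20, SE 0.40, adjusted p = 0.000355) and the cyclooxygenase gene Ptgs2 (log2 fold change −1.91, SE 0.44, adjusted p = 0.00242). Ccl5 and Ptgs2 had a raw count under 20 in all 4 blood loss samples and Il1b in 2 of 4, so the sizes of these changes rest on low counts. Ptprc had a log2 fold change of −0.65 (SE 0.28, adjusted p = 0.0811), which did not pass. It was called lower without Acute blood loss 2 (−0.87) and with the deposited size factors (−1.09).

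No list passed camera in this comparison. The lowest adjusted p was 0.435 at the preset correlation and 0.984 with an estimated correlation, and the lowest for fry was 0.0796. With Normal 1 as the only normal sample, an alternative chosen after seeing the data that assumes the lone sample to vary like the treated groups, 8 genes were called higher and 12 lower, and Il1b was not called (−0.035).

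After acute hypoxia, more genes fell than rose with housekeeping scaling, and those that fell included markers of B cells, T cells and macrophages. In Normal 1, however, the mean log2 level of the B cell markers (6.46) lay within the range of the hypoxia samples (5.87 to 6.61). The fall of the B cell list therefore rests mainly on Normal 2 and Normal 3. The level of the macrophage markers in Normal 1 (5.10) lay below Acute hypoxia 2 (5.66) but above the other hypoxia samples (3.40 to 4.43). It was lower than in Normal 2 and Normal 3 (6.29 and 5.95), so the size of this fall depends on the normal samples used. For T and NK cell markers every normal sample lay above every hypoxia sample (5.29 to 6.01 against 4.40 to 5.01). Tyrobp, a signalling adaptor of myeloid and NK cells, fell from 428 ± 157 (SD, n = 3) to 78.4 ± 8.42 (SD, n = 4; log2 fold change −2.46, SE 0.32, adjusted p = 4.16e-06). Ms4a1 fell from 895 ± 237 to 345 ± 121 (log2 fold change −1.38, SE 0.33, adjusted p = 0.00166), Cd3d from 55.8 ± 10.2 to 20.8 ± 8.43 (log2 fold change −1.39, SE 0.33, adjusted p = 0.00155) and the macrophage marker gene Emr1, which encodes F4/80, from 66.3 ± 19.1 to 12.4 ± 10.1 (log2 fold change −2.53, SE 0.38, adjusted p = 1.7e-05). Emr1 reached a raw count of 20 in 1 of 4 hypoxia samples and stood at −3.18 without Acute hypoxia 2. Tfrc rose from 129 ± 13.6 to 315 ± 219.8 (log2 fold change 1.28, SE 0.38, adjusted p = 0.00848), a call lost without Acute hypoxia 2 (log2 fold change 0.67, adjusted p = 0.0823), and Camp rose from 63.2 ± 34.0 to 279.6 ± 75.9 (log2 fold change 2.10, SE 0.37, adjusted p = 0.00011).

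Of 252 genes tested, 19 were called higher and 83 lower, with 128 at an unadjusted p under 0.05. The groups did not overlap in 42.9% of genes, against 5.71% by chance. The median log2 fold change of all tested genes was −0.49 with housekeeping scaling, 0.02 with TMM factors and −0.04 with the deposited size factors. Calls were 55 higher and 44 lower with TMM factors, 49 and 51 with size factors over the tested genes, 51 and 50 with the deposited size factors, 20 and 65 with all 14 housekeeping genes and 23 and 69 without Rpl19. With TMM and the deposited size factors lower calls were fewer than higher ones. Under all 5 other scalings 18 of the 19 and 44 of the 83 calls were made in the same direction. The 12-sample fit of the design called 25 higher and 141 lower. Higher calls numbered 10 without Normal 3 and 12 without Acute hypoxia 3, and lower calls numbered 45 without Normal 2 and 55 without Normal 3.

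Of 14 tested B cell markers 10 fell and none rose, also when adjusted over the list alone, and with TMM factors 6 fell and 1 rose. They included Cd22, an inhibitory receptor of B cells (log2 fold change −2.05, SE 0.40, adjusted p = 0.000263), Ms4a1, the kinase gene Btk (log2 fold change −1.35, SE 0.30, adjusted p = 0.00106) and the inhibitory Fc receptor gene Fcgr2b (log2 fold change −1.30, SE 0.33, adjusted p = 0.00249). The list median minus that of all tested genes was −0.64. The mean log2 level of the B cell markers in Normal 1, 6.46, lay within the 5.87 to 6.61 of the hypoxia samples. The fall of the list therefore rests mainly on Normal 2 and Normal 3. The adjusted p was 0.287 with camera at the preset correlation, 0.923 with an estimated correlation and 0.0482 with fry. The fry call was lost under all 5 other scalings and without any 1 of Normal 2 (adjusted p = 0.129), Normal 3 (0.105), Acute blood loss 2 (0.0604), 3 (0.0656) or 4 (0.0581), or Acute hypoxia 1 (0.102), 2 (0.0933) or 3 (0.0793).

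Of 13 T and NK cell markers 8 fell and none rose, adjusted over the list alone 9 fell, and with TMM factors 6 fell. Examples were Tcf7 (log2 fold change −1.82, SE 0.32, adjusted p = 0.00011), Cd3e (log2 fold change −1.26, SE 0.30, adjusted p = 0.00166) and Prf1, the pore-forming protein of cytotoxic cells (log2 fold change −1.53, SE 0.33, adjusted p = 0.000709), with a raw count of 20 or more in 2 of 4 hypoxia samples for Cd3e and 1 for Prf1. The list median minus that of all tested genes was −0.76. The list's adjusted p was 0.264 with camera, 0.923 with an estimated correlation and 0.00547 with fry, and the fry call was lost with TMM factors (adjusted p = 0.110), the deposited size factors (0.0995) and size factors over the tested genes (0.0741).

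Of 6 genes of Fc receptors and phagocytosis 5 fell and Cd36 rose (log2 fold change 1.16, SE 0.31, adjusted p = 0.00398), with the same counts adjusted over the list alone. Besides Tyrobp and Fcgr2b, these were Fcer1g, the shared gamma chain of activating Fc receptors (log2 fold change −1.99, SE 0.36, adjusted p = 0.00014), the integrin gene Itgb2 (log2 fold change −1.40, SE 0.27, adjusted p = 0.000228) and 1 other gene. The list median minus that of all tested genes was −0.86, and under each of the 5 other scalings 4 members were called lower and 1 higher. The adjusted p was 0.354 with camera, 0.923 with an estimated correlation and 0.00547 with fry. Of 13 leukocyte common genes 7 fell and 1 rose, also when adjusted over the list alone, and with TMM factors and the deposited size factors 4 fell and 2 rose. Among those that fell were the phosphatase gene Ptpn6 (log2 fold change −1.83, SE 0.29, adjusted p = 4.11e-05) and Ptprc (log2 fold change −0.88, SE 0.27, adjusted p = 0.0124). The call of Ptprc was lost with TMM factors (log2 fold change −0.37), with the deposited size factors (−0.43) and without Normal 2 (−0.79). That list's adjusted p was 0.609 with camera, 0.923 with an estimated correlation and 0.00547 with fry, and the fry call was lost with TMM factors (adjusted p = 0.110). Of 6 granulocyte markers Camp rose, 1 fell and 4 were not called, also when adjusted over the list alone, and with TMM factors 2 rose and none fell. S100a9 had a log2 fold change of 0.95 (adjusted p = 0.102) and was called higher with TMM factors (1.40) and without Normal 1 (1.25).

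Among costimulatory and checkpoint ligands 3 of 7 rose and 2 fell, also when adjusted over the list alone. Cd86 rose (log2 fold change 1.23, SE 0.34, adjusted p = 0.00499), as did Cd83, a marker of activated dendritic and B cells (log2 fold change 1.13, SE 0.40, adjusted p = 0.0247), and Cd274 (log2 fold change 0.80, SE 0.29, adjusted p = 0.0281). Icosl and Cd48 fell, with log2 fold changes of −1.85 (adjusted p = 0.00018) and −1.49 (adjusted p = 0.000245). Housekeeping-scaled Cd86 was 55.4, 44.1 and 33.3 in Normal 1, Normal 2 and Normal 3, against 56.8 to 137 in hypoxia samples. The size of its rise therefore depends on the normal samples used. The call of Cd83 was lost without Normal 2 (0.95), Normal 3 (0.80), Acute hypoxia 3 (0.99) or Acute hypoxia 4 (0.91), and its log2 fold change was 1.81 without Normal 1. The raw count of Cd83 in Normal 2 and Normal 3 was 1.54 and 1.97 times that in Normal 1, against medians of 5.41 and 8.69 over 125 genes. That of Cd274 was lost without Normal 1 (0.56), Normal 3 (0.89), Acute hypoxia 3 (0.74) or Acute hypoxia 4 (0.71).

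Of 10 genes of MHC class II presentation 5 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose. With TMM factors 1 fell and 1 rose, and with the deposited size factors and with size factors over the tested genes 2 fell and 1 rose. H2-Ob fell (log2 fold change −2.19, SE 0.28, adjusted p = 3.32e-06), as did H2-Ab1 (log2 fold change −2.10, SE 0.60, adjusted p = 0.013) and the class II transactivator gene Ciita (log2 fold change −1.19, SE 0.34, adjusted p = 0.00651). H2-Ea-ps was called higher (log2 fold change 1.29, SE 0.51, adjusted p = 0.0451). H2-Eb1 had a log2 fold change of −0.80 (adjusted p = 0.0521), and Cd74 one of 1.21 (adjusted p = 0.12). Without Normal 1, Cd74 was called higher (2.85), H2-Eb1 was called lower (−0.92), as it was without Acute blood loss 2 (−0.80), and H2-Ab1 was not called (−0.30). Calls of H2-Ab1 and Ciita were lost with TMM factors. That of H2-Ab1 was also lost without Acute hypoxia 2 (−2.09) or Acute hypoxia 4 (−2.07), and that of Ciita without Normal 2 (−0.90). The call of H2-Ea-ps was lost without Rpl19 among the housekeeping genes (1.34) and with all 14 housekeeping genes (1.33). It was also lost without Normal 2 (1.10), Normal 3 (0.86), Acute blood loss 1, 3 or 4 (1.29 each), Acute hypoxia 1 (1.21) or Acute hypoxia 3 (1.28), and without Normal 1 it stood at 2.28. The list's adjusted p was 0.992 with camera, 0.995 with an estimated correlation and 0.0300 with fry, and the fry call was lost under all 5 other scalings and without Normal 1 (adjusted p = 0.391), Normal 2 (0.0986) or any 1 hypoxia sample (0.0594 to 0.0933).

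Of 8 erythroid and progenitor genes 2 rose, 1 fell and 5 were not called, also when adjusted over the list alone. Tal1 rose (log2 fold change 3.40, SE 0.78, adjusted p = 0.00345), with a raw count under 20 in all 3 normal samples and 20 or more in 3 of 4 hypoxia samples. Its housekeeping-scaled count was 87.6 in Acute hypoxia 2 and 7.58 to 17.4 in the others, and without that sample its log2 fold change was 2.29 (adjusted p = 0.000102). With TMM factors 3 genes of the list rose and none fell. Other genes that rose included the transcription factor gene Stat4 (log2 fold change 2.09, SE 0.35, adjusted p = 6.82e-05) and the signal transducer of TGF-beta Smad3 (log2 fold change 1.44, SE 0.35, adjusted p = 0.00191). Genes that fell included Il1b (log2 fold change −3.87, SE 0.56, adjusted p = 0.000133), Ccl5 (log2 fold change −3.00, SE 0.35, adjusted p = 1.61e-06), Ptgs2 (log2 fold change −2.78, SE 0.38, adjusted p = 6.18e-06) and Tgfbi (log2 fold change −2.61, SE 0.36, adjusted p = 6.18e-06). Il1b, Ptgs2 and Tgfbi reached a raw count of 20 in 1 of 4 hypoxia samples and Ccl5 in 2, so the sizes of these changes rest on low counts. No list passed camera. With Normal 1 as the only normal sample, on the same assumption, 3 genes were called higher and 19 lower.

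**Figure D2:**
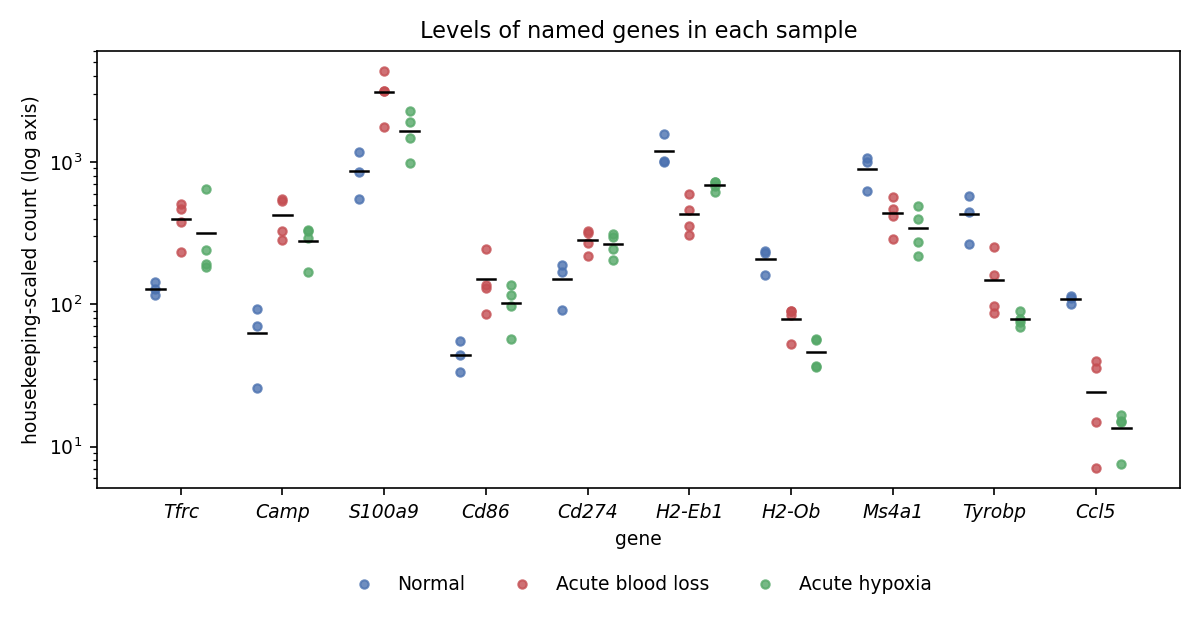
Points are the housekeeping-scaled counts (y axis, log scale) of 10 genes (x axis) in 3 normal, 4 blood loss and 4 hypoxia samples, and black lines are group means. Tfrc, Camp, Cd86 and Cd274 lie higher in both treated groups than in normal samples, and H2-Ob, Ms4a1, Tyrobp and Ccl5 lie lower, in this scaling.

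Between hypoxia and blood loss, 22 of 252 genes were called with housekeeping scaling and 97 with the deposited size factors. Irf1, an interferon-induced transcription factor, was higher after hypoxia, at 316 ± 72.7 against 122 ± 40.7 (SD, n = 4 each; log2 fold change 1.39, SE 0.28, adjusted p = 0.00565), and was the only gene called higher with housekeeping scaling. It was called under all 5 other scalings as well. Casp1, the caspase of the inflammasome, was lower after hypoxia (log2 fold change −1.56, SE 0.35, adjusted p = 0.00721), as were the integrin gene Itgb2 (log2 fold change −1.32, SE 0.29, adjusted p = 0.00721), the lymphocyte inhibitory receptor gene Btla (log2 fold change −1.21, SE 0.30, adjusted p = 0.0118) and Nfkbia, an inhibitor of NF-kappaB (log2 fold change −1.11, SE 0.28, adjusted p = 0.012). Itgb2 reached a raw count of 20 in 1 of 4 blood loss samples. These 4 calls were lost with the deposited size factors and with all 14 housekeeping genes. That of Btla was lost without Acute blood loss 2 (−0.92), and that of Nfkbia without Acute blood loss 2 (−1.13), Acute blood loss 3 (−0.997) or Acute hypoxia 1 (−0.95).

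Of 252 genes 1 was called higher and 21 lower, with 64 at an unadjusted p under 0.05, and the groups did not overlap in 13.1% of genes against 2.86% by chance. The median log2 fold change was −0.25 with housekeeping scaling, 0.00 with TMM factors and 0.60 with the deposited size factors. Calls were 7 higher and 11 lower with TMM factors, 6 and 11 with size factors over the tested genes, 4 and 15 without Rpl19, 5 and 1 with all 14 housekeeping genes and 96 and 1 with the deposited size factors, so which genes were called, and whether more were higher or lower, depended on the scaling. Of the 22 called genes 1 had the opposite sign with the deposited size factors. Of the 21 lower genes 1 was called lower under all 5 other scalings. The 12-sample fit of the design called 4 higher and 39 lower. Lower calls numbered 37 without Normal 1, 12 without Normal 3, 5, 10 and 8 without Acute blood loss 2, 3 and 4, and 11 and 10 without Acute hypoxia 1 and 3. Higher calls numbered 3 without Normal 1 or Acute blood loss 1, 2 without Acute hypoxia 2 and 4 without Acute hypoxia 4.

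All 3 tested stromal and endothelial markers were called lower after hypoxia, also when adjusted over the list alone. They were Pecam1 (log2 fold change −1.04, SE 0.31, adjusted p = 0.0403), Itga6 (log2 fold change −1.33, SE 0.41, adjusted p = 0.0456) and Icam2 (log2 fold change −1.01, SE 0.31, adjusted p = 0.0472), with a raw count of 20 or more in 2, 0 and 1 of 4 blood loss samples. None of the 3 was called with TMM factors or with the deposited size factors, nor without Normal 3 (−1.04, −1.33 and −1.01), Acute blood loss 2 (−0.85, −1.14 and −1.12), 3 (−1.05, −1.15 and −0.98) or 4 (−0.996, −1.50 and −0.98), or Acute hypoxia 1 (−0.90, −1.29 and −0.96), 2 (−0.93, −1.21 and −1.05) or 3 (−1.06, −1.35 and −0.91). Icam2 was also not called without Acute blood loss 1 (−0.95). The list's adjusted p was 0.0796 with camera, 0.621 with an estimated correlation and 0.00958 with fry, and the fry call was lost with the deposited size factors (adjusted p = 0.274). Of 6 genes of Fc receptors and phagocytosis 2 were lower after hypoxia, 3 when adjusted over the list alone, 1 with TMM factors and 0 with the deposited size factors. That list's adjusted p was 0.0796 with camera, 0.733 with an estimated correlation and 0.0308 with fry. The fry call was lost without Normal 3 (0.0567), without any 1 blood loss sample (0.05003 to 0.0943) or any 1 hypoxia sample (0.0571 to 0.105), and the list median was 0.14 with the deposited size factors.

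Of 10 genes of MHC class II presentation none was called, 1 was called higher after hypoxia with TMM factors and 4 with the deposited size factors. Cd74, H2-Aa and H2-Ab1 had log2 fold changes of −0.13 (adjusted p = 0.906), 0.18 (adjusted p = 0.871) and 0.48 (adjusted p = 0.675). Of 14 B cell markers 1 was lower, also when adjusted over the list alone. Of 13 T and NK cell markers 2 were lower, and 3 when adjusted over the list alone. With the deposited size factors 3 B cell and 2 T and NK cell markers were higher and none lower. Cd28 was among the lower ones in the reported fit (log2 fold change −1.60, SE 0.40, adjusted p = 0.0118), a call lost without Acute blood loss 2 (−1.59, adjusted p = 0.0662) or Acute blood loss 4 (−1.41, adjusted p = 0.0949), and its raw count was 20 or more in 1 sample of each group. Neither Tfrc (log2 fold change −0.33, adjusted p = 0.615) nor Camp (−0.60, adjusted p = 0.242) passed the threshold, and Tfrc was called lower after hypoxia without Acute hypoxia 2 (−0.94).

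The responses to blood loss and hypoxia, each against normal, resembled each other. Across the 252 genes the log2 fold changes had a Pearson correlation of 0.826 and a Spearman correlation of 0.778, and 81.7% of genes had the same sign. Genes are not independent replicates. Both comparisons share the normal samples. Counts simulated anew for all 11 samples without group differences, with both comparisons sharing the simulated normal samples, gave means of 0.500, 0.479 and 66.8% over 100 simulations. Genes were drawn independently, so the simulations leave out differences between the real normal samples that many genes share. The covariance was 0.744 against a simulated 0.0634, a difference of 0.680. In both comparisons 11 genes rose, among them Camp, Tfrc, Tal1, Cd86, Cd36 and Cd274, where independent lists would share 1.88. In both 32 genes fell, among them H2-Ab1, H2-Ob, Ms4a1, Cd3d, Tcf7, Il1b and Ccl5, where independent lists would share 14.2, and no gene was called in opposite directions. Some of these calls rest on single samples. After hypoxia H2-Ab1 was not called without Normal 1, nor was Tfrc without Acute hypoxia 2. Over 100 simulations of unchanged groups with shared normal samples, 0.010 genes rose in both on average and 0 fell in both. That value leaves out the effects and the value for independent lists leaves out the shared samples. With 3 normal samples the controls could not be divided into parts of at least 2, so part of the excess may come from the shared controls. A difference between the normal samples and all treated samples, whatever its source, would also enter both comparisons. The raw ratio of H2-Ab1 to H2-Aa set them apart in this way, at 0.272 to 0.328 in normal against 0.0242 to 0.0362 in treated samples. Whether a technical difference contributes to the resemblance was not tested.

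**Figure D3:**
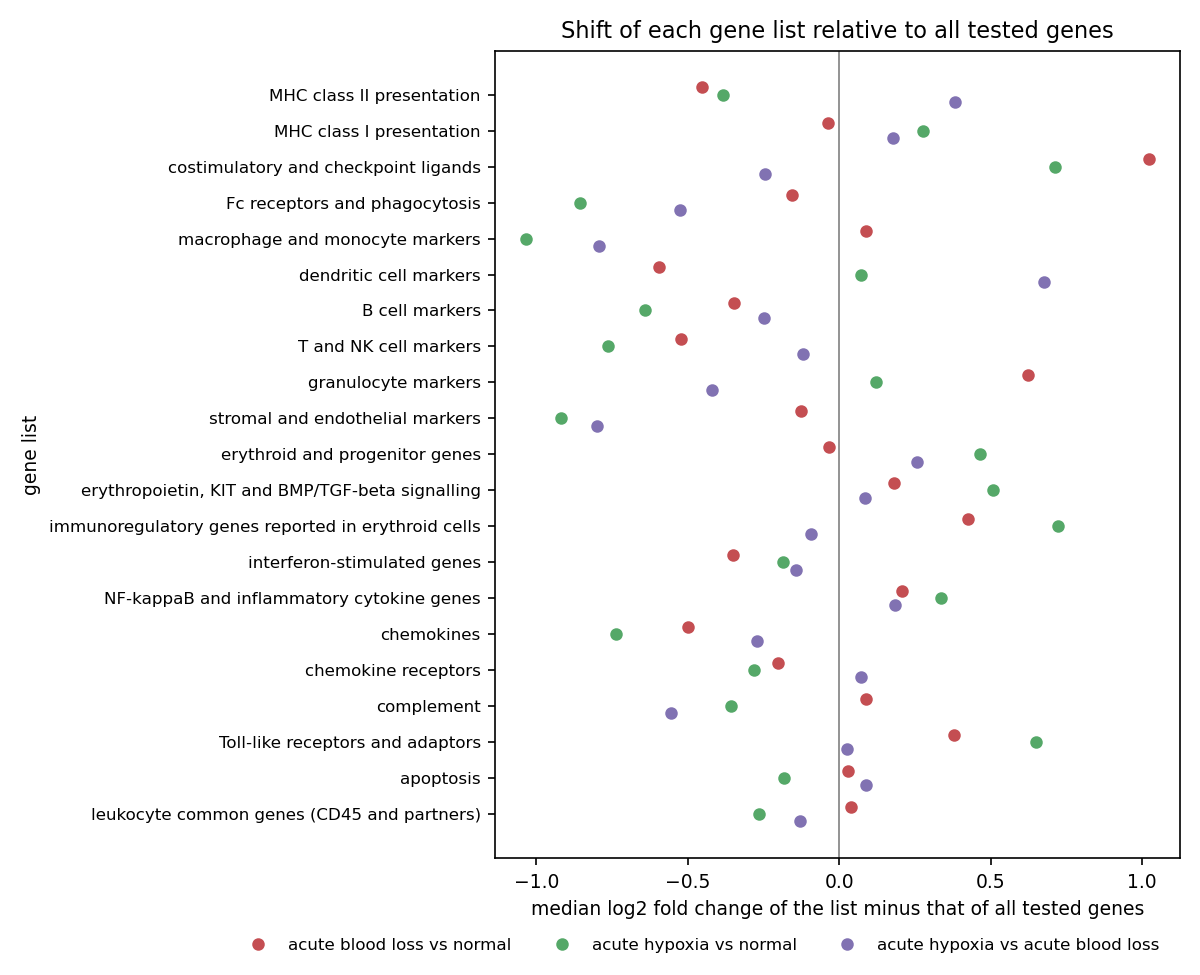
Points give, for each of 21 gene lists (y axis), the median log2 fold change of its members minus that of all tested genes (x axis) in each of the 3 comparisons. In hypoxia against normal B cell markers lie at −0.64 and T and NK cell markers at −0.76, and costimulatory ligands lie at 1.02 in blood loss against normal.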

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

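The tests of leukocyte share and of housekeeping scaling for the hypoxia markers, and the tests of a counting ceiling and of scaling for the normal samples, were chosen after the results were seen, and the housekeeping scaling test replaced an earlier one whose standard error took the markers as independent.

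In 12 of 150 groups of 4 samples, 1 sample lay apart from the other 3 by Dixon's criterion, where chance gives about 1 in 20, or 7.5. In Acute blood loss 3, the shallowest sample, housekeeping-scaled counts were 51.9 for Tcf7 against 29.5 to 33.1 in the other 3 blood loss samples. In the same sample Igf2r stood at 37.1 (others 12.7 to 15.5), Itgb2 at 66.7 (others 48.4 to 49.2) and Cd247 at 66.7 (others 35.1 to 36.9). The library factor of Acute blood loss 3 was 0.135, so its values for these genes and Tcf7 stand for raw counts under 20. These differences therefore rest on low counts. Acute blood loss 2 held 5658 of H2-Aa (others 3003 to 3432) and 2578 of H2-Ea-ps (others 1206 to 1298). H2-Ob was 52.3 in Acute blood loss 1, below 84.0 to 90.0 in the others. Acute hypoxia 2 stood apart with 642 for Tfrc (others 184 to 239), 87.6 for Tal1 (others 7.58 to 17.4) and 27.5 for Emr1 (others 6.20 to 7.99). Ctss was 196 in Acute hypoxia 3 (others 147 to 153), and Tcf7 was 48.9 in Acute hypoxia 4 (others 20.7 to 24.0).

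The numbers of calls were set against all 35 splits of the samples of each comparison into groups of the same sizes. Blood loss against normal gave 68 calls and the highest other split 25. Hypoxia against normal gave 102 and the highest other split 69, and hypoxia against blood loss gave 22 and the highest other split 5. In each comparison 1 of the 35 splits, the real one, gave as many calls, so chance assignment of samples can be excluded at a share under 0.05, for each comparison taken by itself.

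Of 31 tested markers of B cells, T and NK cells and macrophages, 20 were called lower after hypoxia than in normal samples, and none of the 3 lists passed camera. The mean log2 levels of the B cell and of the macrophage markers in Normal 1 lay within the range of the hypoxia samples. For the macrophage markers only Acute hypoxia 2 lay above Normal 1. A lower share of all leukocytes among the enriched cells would lower granulocyte and B cell markers alike, but the granulocyte minus B cell score rose by 1.10 log2 units, with 1.48 to 2.39 in hypoxia against 0.74 to 1.07 in normal samples. The difference rests on Camp, since without it the score rose by 0.67, with 1.55 to 2.41 in hypoxia overlapping 1.13 to 1.63 in normal samples, and 1 of the 6 granulocyte markers was called lower. A lower share of leukocytes therefore cannot be told apart from a change in the kinds of leukocyte. Of the 20 markers, 13 were also called lower under each of the 5 other scalings, which argues against housekeeping scaling as the whole cause for these 13. The other 7 lost the call under at least 1 scaling, and for them scaling and a true fall cannot be told apart, since a lost call does not show which scaling is right. A change in the kinds of leukocyte present, or in transcripts within erythroid cells, stays open and untested, and either could give these values.

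Genes called higher after blood loss may include background counts, because those samples are the shallowest. After subtraction of each sample's lower quartile, 64% of them were still called higher, between the bounds of 50% and 75%. The bounds were set before this test was run, while the subtraction itself was chosen after the data were seen. The background explanation therefore cannot be told apart from a true rise for these genes as a set, and control probes were not used here. A response to blood loss, the difference the design names, stays open as well.

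Cd74, H2-Aa, H2-Ab1, H2-Ea-ps, B2m, Cd83 and Rpl19 were low for their depth in Normal 2 and Normal 3. Among the next genes by this measure were S100a9, Tcf7, Lck and Cd86. Their raw ratios to Normal 1 also lay under the median ratios in Normal 2 and Normal 3. A counting ceiling shared by all probes is argued against by at least 15 probes with a higher count than Cd74 in each of these samples. Library scaling is argued against by the raw ratio of Cd74 to H2-Eb1, which was 7.93 times higher in Normal 1 than in the higher of the others. The cause remains unknown, and no biological explanation was tested.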

How the results depend on the processing

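The 12-sample fit is that of the design, and leaving out Normal 4 was chosen after the data were seen. Housekeeping genes without Rpl19, size factors over the tested genes, lower quartile subtraction, Normal 1 as the only normal sample, a count of 20 in at least 3 samples, thinned counts, leaving out 1 sample with the genes of the 11-sample fit and the detection thresholds of 10 and 40 were tests chosen after the data were seen. Library scaling, the choice of normal samples, thinning of all samples to the shallowest total and the count filter each changed the counts of calls. Results with Normal 1 alone assume that this sample varies like the treated groups, which supply all the spread. Causes were not tested except where stated. Alternatives that need control probes were not run, and the DESeq2 Wald test gave no list tests. The deposited size factors named below were recomputed by the deposited method over the 11 samples, except in limma on the deposited values.

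In blood loss against normal, 25 higher and 43 lower calls became 39 and 32 with TMM factors, 13 and 114 with the deposited size factors, 14 and 85 with all 14 housekeeping genes, and 11 and 117 with limma on the deposited values. They were 183 and 64 without the count filter, where 547 genes were tested, 10 and 13 with a count of 20 in all samples, where 61 were tested, 26 and 48 with a count of 20 in at least 3 samples, where 282 were tested, and 16 and 62 after lower quartile subtraction. They were 33 and 73 with all 12 samples, 8 and 12 with Normal 1 alone and 18 and 20 after thinning. Leaving out 1 sample at a time gave 13 to 30 higher and 20 to 58 lower.

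In hypoxia against normal, 19 higher and 83 lower calls became 55 and 44 with TMM factors, 51 and 50 with the deposited size factors, 49 and 51 with size factors over the tested genes and 36 and 31 with limma. They were 34 and 162 without the count filter, 8 and 17 with a count of 20 in all samples, 20 and 103 with one in at least 3 samples, 25 and 141 with all 12 samples, 3 and 19 with Normal 1 alone and 9 and 40 after thinning. Leaving out 1 sample gave 10 to 19 higher and 45 to 100 lower.

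In hypoxia against blood loss, 1 higher and 21 lower became 7 and 11 with TMM factors, 96 and 1 with the deposited size factors, 5 and 1 with all 14 housekeeping genes, 100 and 1 with limma, 4 and 31 with the DESeq2 Wald test and 2 and 26 with only the 2 groups compared. They were 5 and 230 without the count filter, 0 and 4 with a count of 20 in all samples, 2 and 30 with one in at least 3 samples, 4 and 39 with all 12 samples, 4 and 15 without Rpl19, 6 and 11 with size factors over the tested genes, 1 and 5 after lower quartile subtraction and 1 and 12 after thinning. Leaving out 1 sample gave 1 to 4 higher and 5 to 37 lower.

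With the replicate number as a block, calls were 23 and 41 in blood loss against normal, 20 and 84 in hypoxia against normal, and 1 and 16 in hypoxia against blood loss. Of 10 same-numbered pairs 2 had a correlation over 0.1, so the numbers do not pair the samples. Of 130 gene values followed, 121 kept their direction and side of the threshold under the replicate block and 9 lost the call.

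Lists passing fry numbered 0 in blood loss against normal in the reported fit, 14 with the deposited size factors and with limma, 7 without Rpl19, 6 with all 14 housekeeping genes, 5 after lower quartile subtraction, 3 with a count of 20 in all samples, with all 12 samples and with size factors over the tested genes, 2 with TMM factors and 0 to 2 on leaving out 1 sample. In hypoxia against normal 8 passed, against 14 with all 12 samples, 5 with the deposited size factors and with a count of 20 in all samples, 4 with limma and after thinning and 2 with Normal 1 alone. In hypoxia against blood loss 2 passed, against 13 with the deposited size factors and with limma, 4 with TMM factors, 1 with the replicate block and after thinning, 0 with a count of 20 in all samples and 1 to 4 on leaving out 1 sample. At the preset correlation camera passed no list in the reported fit. Without the count filter it passed 2 in blood loss against normal and 7 in hypoxia against blood loss. With Normal 1 alone it passed 3 in blood loss against normal and 1 in hypoxia against normal, and on leaving out 1 sample 0 to 1 in hypoxia against blood loss. With an estimated correlation none passed in any setting that gave a test.

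Values with a call in the reported fit or the alternative that reversed in hypoxia against blood loss were, with the deposited size factors and with limma on the deposited values, 0.050 and 0.063 for Tcf4, 0.80 and 0.78 for Cd274 and 0.67 and 0.69 for Ptprc. Lists with a fry call in either fit that reversed there had medians of 0.43 and 0.37 for costimulatory and checkpoint ligands, 0.14 and 0.15 for Fc receptors and phagocytosis, 0.66 and 0.68 for erythropoietin, KIT and BMP/TGF-beta signalling, 0.53 and 0.48 for immunoregulatory genes, 0.42 and 0.56 for interferon-stimulated genes, 0.81 and 0.81 for NF-kappaB and inflammatory cytokine genes, 0.71 and 0.64 for chemokine receptors, 0.63 and 0.60 for Toll-like receptors and adaptors, 0.69 and 0.63 for apoptosis and 0.54 and 0.58 for leukocyte common genes. Other list medians that changed sign there were 0.42 and 0.34 for B cell, 0.46 and 0.49 for T and NK cell and 0.17 and 0.21 for granulocyte markers, 0.32 and 0.45 for chemokines, 0.036 and 0.066 for complement and 0.78 and 0.83 for MHC class I presentation. In blood loss against normal the list of erythropoietin, KIT and BMP/TGF-beta signalling stood at −0.51 and −0.49 under these settings. In hypoxia against normal the immunoregulatory list reversed in fry's direction, with medians of 0.76 with TMM factors, 0.69 with the deposited size factors, 0.70 with limma, 0.80 with a count of 20 in all samples and 0.68 with size factors over the tested genes, as did Toll-like receptors with TMM factors at 0.69 and MHC class II presentation with a count of 20 in all samples at 0.33.

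Of 130 gene values, 110 kept direction and side of the threshold with TMM factors, 93 with the deposited size factors, 103 with all 14 housekeeping genes and 75 with Normal 1 alone. With the DESeq2 Wald test 5 of 124 gained a call and 0 lost one, and the others kept direction and side. It gave no p-value for H2-Aa and H2-Ab1 in any of the 3 comparisons. MHC class II genes detected in all blood loss samples numbered 10 at a raw count of 10, and MHC class I genes 4 at a raw count of 10 and 1 at 40. The correlation between the 2 responses was 0.748 to 0.881 across settings.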

Other observations

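The test of the H2-Ab1 to H2-Aa ratio was chosen after the result was seen.

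Members of further lists were called lower after hypoxia, and none of these lists passed camera. Of 3 tested stromal and endothelial markers 2 fell against normal, among them Icam2 (log2 fold change −1.71, SE 0.27, adjusted p = 4.2e-05, edgeR), also when adjusted over the list alone. The adjusted p was 0.354 with camera, 0.923 with an estimated correlation and 0.00119 with fry. Of 4 chemokine genes 2 fell, with TMM factors 2 fell and 1 rose, and those that fell in the reported fit were Ccl5 and Ccl3 (log2 fold change −1.86, SE 0.34, adjusted p = 0.000153), with adjusted p of 0.437, 0.923 and 0.00119. Of 11 interferon-stimulated genes 4 fell, 6 when adjusted over the list alone, and with TMM factors 3 fell and 1 rose. Adjusted p was 0.733 with camera, 0.967 with an estimated correlation and 0.00926 with fry, which TMM factors ended (adjusted p = 0.110). Of 4 macrophage and monocyte markers 2 fell, 3 when adjusted over the list alone and 1 with TMM factors (adjusted p 0.558 with camera, 0.923 with an estimated correlation and 0.0527 with fry).

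After blood loss 2 of 4 tested genes of the dendritic cell list fell, among them the transcription factor gene Irf8 (log2 fold change −1.24, SE 0.29, adjusted p = 0.00265, edgeR), also when adjusted over the list alone, and 1 fell with TMM factors. The 4 tested genes were Irf4, Irf8, Ccr7 and Batf. No other member of the list, such as Flt3, Xcr1 or Itgax, was tested, so these counts cannot be read as a fall of dendritic cells. That list's adjusted p was 0.435 with camera, 0.984 with an estimated correlation and 0.0796 with fry. None of these 4 was called after hypoxia, and the difference between hypoxia and blood loss was called in none of them, although 2 were higher after hypoxia when adjusted over the list alone or with TMM factors, and 3 with the deposited size factors. Of 8 apoptosis genes none was called after blood loss and 4 fell after hypoxia. These 4 calls were lost with TMM factors, the deposited size factors and size factors over the tested genes, where 2 other members were called higher. With all 14 housekeeping genes no member was called, and without Rpl19 1 was called lower. The list median was −0.68 in the reported fit, −0.13 with TMM factors and −0.52 with all 14 housekeeping genes. Adjusted p for hypoxia was 0.992 with camera, 0.995 with an estimated correlation and 0.0684 with fry.

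The raw ratio of H2-Ab1 to H2-Aa, the chains of one class II molecule, was 0.328, 0.289 and 0.272 in Normal 1, Normal 2 and Normal 3 and 0.0242 to 0.0362 in the 8 other samples. The difference was 9.77-fold, with a two-sided exact permutation p = 0.00606 over 165 arrangements, the smallest they can give. The separation was noticed in the data before it was tested and fixes this p-value, which therefore adds nothing to it. A ratio within a sample does not depend on scaling. Whether the difference comes from the treatments or from a technical difference between normal and treated samples was not tested.

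Under the deposited size factors, recomputed over the 11 samples, the median log2 fold change of tested genes after blood loss was −0.63. Size factors over the tested genes gave −0.033, which their construction sets near 0. With housekeeping scaling the median was −0.24 over the 252 tested genes and 0.32 over the 547 genes without the count filter. The deposited factors are computed over all genes, so genes under the filter weigh in them. The cause was not tested further.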
